A study of Homo sapiens with 9 samples.

How the data were processed

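RNA of 9 xenograft tumours of LoVo, a human colon cancer cell line, was measured on Affymetrix expression arrays, 3 arrays in each of 3 groups. Per the labels' protocols, the cells carried either an empty retroviral vector or the same vector with LIN28B, and grew under the skin of nude mice; tumours were stripped of other tissue and homogenised in RIPA buffer, RNA was isolated with a mirVana kit, and biotin-labelled cRNA was prepared by the Affymetrix protocol. The deposited table holds log2 intensities made by the authors, used without further scaling; which normalization the authors applied is not given in the sources used here. The titles number the samples as biological replicates without saying whether they are separate animals or separate transductions, so each p-value measures the spread among these samples. Array values have no counting depth, and the number of arrays, 3 per group, limits the precision. Mouse RNA from host tissue in a tumour can bind human probes, and no separation of the species was possible from these values.

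The table held 28829 transcript clusters (the array's units of measurement, each built from several probes). Of these, 19291 carried 1 gene symbol, 1735 several and 7803 none; the gene names were checked against the RefSeq gene table of GRCh38.p14, in which 19260 Entrez identifiers of single-gene clusters were found and by which 0 symbols had to be updated. Clusters with several names or none were left out of the gene comparisons and counted apart. Of the 18372 genes left, 682 had more than 1 cluster, and the cluster with the highest mean over the 9 arrays stood for the gene. HMGA2, IGF2 and H19 had no single-gene cluster and are not analysed here.

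Genes were compared with limma 3.58.1 in R 4.3.3: a linear model with 1 mean per group was fitted to all 9 arrays, so that the 3 groups shared 1 estimate of the spread (6 residual degrees of freedom, 2.66 prior degrees of freedom from eBayes). The 4 comparisons were LIN28B primary tumours against vector primary tumours, metastases of LIN28B tumours against LIN28B primary tumours, metastases against vector primary tumours, and the mean of both LIN28B groups against vector primary tumours. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes, with no fold threshold and no filter on dim genes. Errors of fold changes are limma's moderated standard errors, and errors of group means are SDs of 3 arrays. Annotation, tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

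The genes to be named were fixed by a rule: LIN28B; the 12 largest rises and 12 largest falls of the first 2 comparisons and the 5 largest of each in the other 2, among genes past the threshold whose 3 arrays of each group did not overlap; up to 4 members with the smallest p of each gene list; and LIN28A, HMGA2, IGF2BP1, LGR5, PROM1, MYC, DICER1, IGF2 and H19 where measured. XIST and Y-linked genes were left out. Not every gene that the rule gives is described below. The comparisons, this rule, the alternatives and 29 gene lists were fixed before the data were examined. The lists were LIN28 and let-7 targets, intestinal stem cell, Wnt targets, enterocyte differentiation, goblet cell, enteroendocrine and Paneth cell, proliferation, mesenchymal transition, epithelial junction and keratin, hypoxia, endoplasmic reticulum stress and amino acid response, ribosome biogenesis, ribosomal protein, oxidative phosphorylation, TGF-beta and BMP response, interferon response, NF-kappaB and chemokine, cholesterol synthesis, p53 targets, matrix proteases and invasion, and markers of fibroblasts and smooth muscle, endothelium, myeloid and lymphoid cells, hepatocytes, lung epithelium, skeletal muscle, adipocytes, skin keratinocytes and erythroid cells. None was chosen on these samples.

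Each list with at least 5 measured members was tested with limma's camera at a preset correlation of 0.01, which compares the list with all other genes, adjusted over the 29 lists of a comparison. Beside it stand camera with a correlation estimated from the arrays, limma's fry, which asks whether the members moved on balance in a single direction, and the members called when p was adjusted over the list alone. A list's fold change is the median or mean of its members.

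The alternatives were quantile normalization, centring each array on its median, leaving out the genes below the median level, the mean of a gene's clusters, every single-gene cluster by itself, eBayes with trend and robust, limma's arrayWeights, a fit of only the groups compared, the replicate number as a block, and leaving out each array in turn. The pseudocount alternatives did not apply, since the deposited values are log2. Quantile normalization together with leaving out LIN28B primary replicate 3 was added after seeing the data. The pipeline was tested on simulated data with 18372 genes and the spread of these arrays: of 100 genes given a log2 change of 1, 69 were recovered in the first comparison and 77 in the second, and of 100 given a change of 2, 96 in each. False calls made up 7.82% and 6.49% of the simulated calls. The simulation gave each gene the same spread in all 3 groups and drew the genes independently. The real groups differed, with median SDs of 0.09 in vector primaries, 0.21 in LIN28B primaries and 0.14 in metastases. These rates therefore need not hold for the real comparisons.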

Results

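Gene expression was measured in 3 groups of LoVo xenograft tumours. There were 3 primary tumours of cells with the empty vector (vector primaries), 3 primary tumours of cells with constitutive LIN28B (LIN28B primaries), and 3 metastases that arose from LIN28B tumours. LIN28B is an RNA-binding protein that blocks the maturation of let-7 microRNAs. The design text states that vector tumours gave no metastases, so a vector metastasis group does not exist, and the site of the metastases is not stated. The 9 arrays had median log2 intensities from 7.03 to 7.15 and lowest and highest values of 2.75 and 14.63. The SD of the values over an array was 2.09, 2.10 and 2.12 in the metastases and 2.13 in LIN28B primary replicate 2, against 2.20 to 2.22 in the other arrays.

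The arrays of a group lay close together with 1 exception. Correlations across genes (genes are not independent replicates) ran from 0.992 to 0.995 among the vector primaries and from 0.989 to 0.991 among the metastases, but from 0.940 to 0.986 among the LIN28B primaries. LIN28B primary replicate 3 had a mean correlation of 0.978 with the metastases and 0.968 with the vector primaries. With LIN28B primary replicates 1 and 2 it had 0.947, while these correlated with each other at 0.986. An SD above 1 was found for 462 genes in the LIN28B primaries, against 18 in the vector primaries and 20 in the metastases. The first 3 principal components held 42.3%, 27.4% and 13.3% of the variance. On component 1, LIN28B primary replicate 3 scored 28.14, within the metastases' range of 27.07 to 31.50, and its fellow replicates scored -41.02 and -43.21. On component 3 it stood apart from every other array, at 39.12 against at most 11.87.

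**Figure D1:**
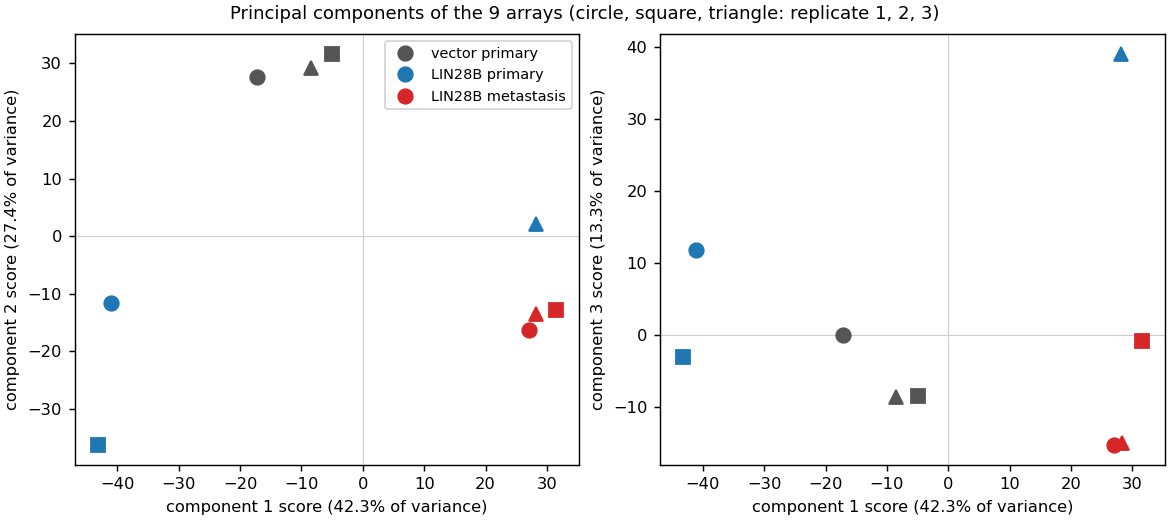
Scores of the 9 arrays on principal components 1 and 2, and on components 1 and 3, of the log2 values, coloured by group; each point is 1 array. LIN28B primary replicate 3 lies with the metastases on component 1 (28.14) and alone on component 3 (39.12).

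The probes for LIN28B itself gave low values in every array. The vector primaries read 4.25, 4.58 and 4.05 (log2), the LIN28B primaries 4.55, 4.58 and 4.83, and the metastases 5.39, 5.44 and 4.78. The lower quartile of all values of an array was 5.39 to 5.61. LIN28B did not pass the test between LIN28B and vector primaries (log2 fold change 0.36 ± 0.20 SE, n = 3 arrays per group, limma adjusted p = 0.435) or between metastases and LIN28B primaries (0.55 ± 0.20, adjusted p = 0.172). For both LIN28B groups against vector primaries the change was 0.64 ± 0.17 (adjusted p = 0.0768), past the threshold without metastasis replicate 3 (adjusted p = 0.0439). LIN28B was higher in the metastases than in the vector primaries (0.91 ± 0.20, adjusted p = 0.0320). That call was lost without vector primary replicate 1 (adjusted p = 0.120) or 3 (0.121) and without metastasis replicate 1 (0.110) or 2 (0.0977), and after quantile normalization (0.0616). Where these probes lie on the transcript was not known, so their values do not check the labels. LIN28A, the paralog, did not pass in any comparison and had a log2 fold change of 0.05 between LIN28B and vector primaries (adjusted p = 0.947).

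The first comparison, LIN28B primaries against vector primaries, asks what constitutive LIN28B changes in the primary tumour. LGR5, a receptor that marks intestinal stem cells, rose 9.13-fold (log2 fold change 3.19 ± 0.54 SE, n = 3 arrays per group, limma adjusted p = 0.0289). PROM1, the CD133 surface protein used as a stem and progenitor cell marker, rose 7.36-fold (2.88 ± 0.36, adjusted p = 0.00857). CFTR, the chloride channel of secretory epithelia, rose 9.61-fold (3.26 ± 0.47, adjusted p = 0.0145). SLC2A3, the glucose transporter GLUT3, was 13.4-fold lower, with 12.06 ± 0.23 in vector and 8.32 ± 0.17 in LIN28B primaries (mean log2 ± SD, adjusted p = 1.64e-04). Copies of SNORD116, small nucleolar RNAs of the imprinted Prader-Willi region, gave the largest falls. SNORD116-24 fell (-4.78 ± 0.81, adjusted p = 0.0289), and SNORD116-1 (-4.27 ± 0.45, adjusted p = 0.00415) and SNORD116-21 (-3.86 ± 0.40, adjusted p = 0.00363) fell with it. In the LIN28B primaries SNORD116-24 read 6.80, 7.28 and 3.96, SNORD116-1 5.05, 5.17 and 3.65, and SNORD116-21 4.16, 3.98 and 3.42. Most of these values lie under the arrays' lower quartile of 5.39 to 5.61, near background, so the size of the falls is uncertain. RPS6KA6, a ribosomal S6 kinase, fell as well (-3.22 ± 0.19, adjusted p = 5.61e-04), from 7.54, 7.91 and 7.10 to 4.19, 4.22 and 4.50, which is near background too, so that its size is uncertain. PRRX1, a homeobox factor of mesenchyme, also fell (-3.16 ± 0.22, adjusted p = 6.57e-04). Other large falls were those of NQO1 (-2.97 ± 0.59), the zinc finger gene ZNF738 (-2.80 ± 0.25), LIX1 (-2.79 ± 0.31, to 5.38, 5.51 and 5.63, near background) and MPP1 (-2.67 ± 0.31). Among the other rises were PON3, a lactonase (1.85 ± 0.21), S100P, a calcium-binding protein (2.16 ± 0.28), and CD24, a surface glycoprotein (1.70 ± 0.21). SPINK1 (2.41 ± 0.47, from a level near background), LURAP1L, POF1B, MTND2P28, SLC44A4 and EFNB2 also rose more than CD24. In all, 365 of 18372 genes changed, 126 upwards and 239 downwards, and 3085 had an unadjusted p under 0.05. Over 2-fold, 43 rose and 114 fell. Of the 24 largest rises and falls, 11 kept their call whichever array was left out, among them PROM1, SLC2A3, SNORD116-1, RPS6KA6 and PRRX1. CFTR was lost without vector primary replicate 2 (adjusted p = 0.0667) or 3 (0.0808), and S100P (0.0551) and CD24 (0.0514) without vector primary replicate 3. LGR5 was lost without vector primary replicate 2 (0.105) or 3 (0.128), LIN28B primary replicate 2 (0.0604) or metastasis replicate 3 (0.0604). SNORD116-24 was lost without vector primary replicate 1, 2 or 3 (0.0644, 0.102 and 0.129) or metastasis replicate 1, 2 or 3 (0.0599, 0.0518 and 0.0543). The count was 2706 genes without LIN28B primary replicate 3 and 166 without LIN28B primary replicate 2. It was 169, 97 and 70 without vector primary replicates 1, 2 and 3, and 167, 182 and 144 without metastasis replicates 1, 2 and 3. With only the 6 arrays compared 36 genes passed. SLC2A3, RPS6KA6, PRRX1, ZNF738 and LIX1 were among these, and PROM1 (adjusted p = 0.0811), LGR5 (0.0760) and CFTR (0.0944) were not.

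**Figure D2:**
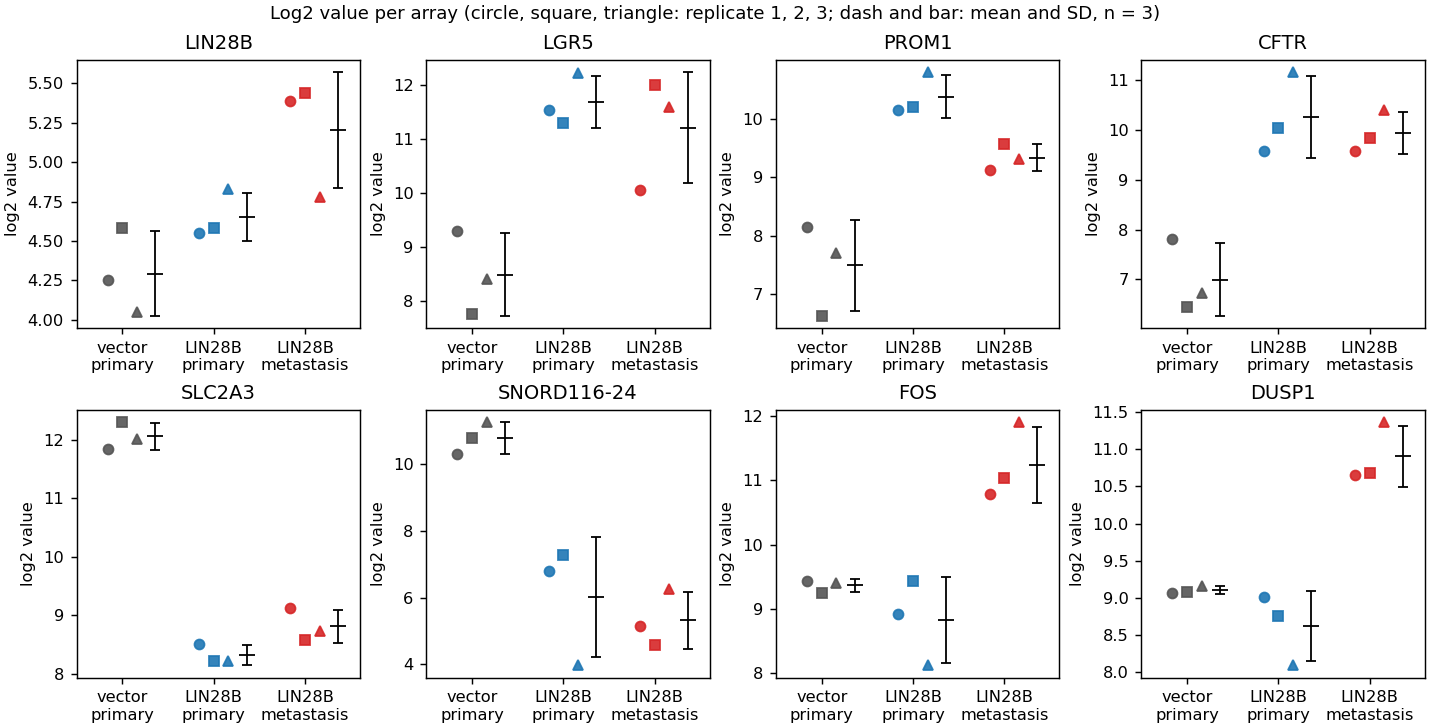
Log2 intensity of 8 genes in each of the 9 arrays, by group; circles, squares and triangles are replicates 1, 2 and 3, and the dash with its bar is the mean ± SD of 3 arrays. SLC2A3 lies between 8.21 and 9.13 in the 6 LIN28B arrays and at 11.85 or above in the vector primaries, and FOS and DUSP1 lie at 10.66 or above in the metastases alone.

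Between vector and LIN28B primaries 9 gene lists passed at the preset correlation between genes. Ribosomal protein genes were higher (median log2 fold change 0.24, 23 measured members, camera adjusted p = 1.70e-06). This call and those of the 8 other lists were lost with an estimated correlation (adjusted p = 0.834 each), and fry called 0 lists, so all 9 rest on the preset correlation. RPS23 was called over all genes (0.83, adjusted p = 0.0471), and 2 members when adjusted over the list alone. Oxidative phosphorylation was higher (median 0.16, 27 members, adjusted p = 0.00412). COX6C (1.42) and NDUFB5 (0.98), subunits of respiratory complexes, rose, and 3 members passed adjusted over the list alone. LIN28 and let-7 targets were higher (median 0.09, 26 members, adjusted p = 0.0364). CDK6, a cell cycle kinase, rose (1.00, adjusted p = 0.0312), IGF1R had 1.05 (adjusted p = 0.0721) and IGF2BP2 0.74 (adjusted p = 0.0563), and 3 members passed adjusted over the list alone. The goblet cell list was higher (median 0.12, 19 members, adjusted p = 0.0364), and its 1 called member, over all genes and adjusted over the list alone, was TFF1, a secreted trefoil peptide (1.46). Hypoxia genes were lower (median -0.13, mean -0.33, 29 members, adjusted p = 0.0235). Beside SLC2A3, those that fell were ANGPTL4 (-2.11), the growth factor VEGFA (-0.67), the glucose transporter SLC2A1 (-0.96) and NDRG1 (-0.62). Adjusted over the list alone, 10 hypoxia genes were lower and 2 higher. Cholesterol synthesis was lower (median -0.40, 18 members, adjusted p = 0.00769), with 0 members called by limma over all genes and 7 lower and 1 higher adjusted over the list alone. Fibroblast and smooth muscle markers were lower (median -0.10, 22 members, adjusted p = 0.00769), with 0 called by limma and 1 adjusted over the list alone. COL1A1, a collagen chain, had -0.67 (adjusted p = 0.0558). Proliferation was lower (median -0.17, 34 members, adjusted p = 0.0277) with 0 members called by limma either way. Genes with mean levels of 9.68 and 11.02 had median log2 fold changes of -0.103 and -0.109 in this comparison. The hypoxia median of -0.13 and part of the proliferation median may therefore go with level. Matrix proteases and invasion were lower (median -0.23, 25 members, adjusted p = 0.0364). PLAT, the tissue plasminogen activator, fell (-1.91, adjusted p = 0.00189), and adjusted over the list alone 6 members were lower and 1 higher. The ribosomal protein call held whichever array was left out. Without LIN28B primary replicate 1, oxidative phosphorylation (adjusted p = 0.162) and LIN28 and let-7 targets (0.168) were lost. Without LIN28B primary replicate 2, goblet cell (0.479, with a mean of -0.02), LIN28 and let-7 targets (0.0649), proliferation (0.125) and matrix proteases (0.0753) were lost. Without LIN28B primary replicate 3, hypoxia (0.600), fibroblast markers (0.216), matrix proteases (0.179), proliferation (0.176) and cholesterol synthesis (0.118) were lost. Gained there were interferon response upwards (adjusted p = 1.97e-04), Wnt targets downwards (0.00755) and enterocyte differentiation upwards (0.00766). The intestinal stem cell list was gained upwards without vector primary replicate 1 (0.0385) or 3 (0.0333) or LIN28B primary replicate 2 (0.0197), and Wnt targets downwards without vector primary replicate 1 (0.0452). Without vector primary replicate 2, goblet cell (0.365), proliferation (0.135), matrix proteases (0.0826), LIN28 and let-7 targets (0.0649), hypoxia and cholesterol synthesis (0.0597 each) were lost, which left 3 lists. Without vector primary replicate 3, LIN28 and let-7 targets were lost (0.0584). After quantile normalization hypoxia (0.0523) and proliferation (0.0986) did not pass. Without the dimmer genes cholesterol synthesis (0.0723), hypoxia (0.0699), matrix proteases (0.159) and proliferation (0.135) were lost, and too few fibroblast markers were left to test. The goblet cell median moved to 0.22, -0.01 and 0.18 without vector primary replicates 1, 2 and 3, and to 0.00 and 0.39 without LIN28B primary replicates 2 and 3, with 5 members higher in the last. In the order of the LIN28B primary replicate left out, oxidative phosphorylation had medians of 0.02, 0.07 and 0.29, with 8 members higher in the last, and hypoxia -0.21, -0.23 and -0.08. Proliferation had -0.28 and -0.11 without LIN28B primary replicates 1 and 3, and fibroblast markers -0.15 without replicate 2.

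The 20 other lists did not pass between LIN28B and vector primaries (camera adjusted p from 0.0817 to 0.976). In the intestinal stem cell list (median 0.07, adjusted p = 0.0817) 3 of 23 members rose, LGR5, PROM1 and CD24, and 4 adjusted over the list alone. Wnt targets had a median of -0.40 (adjusted p = 0.0861); without LIN28B primary replicate 3 it was -0.78, with 12 members lower and 2 higher (adjusted p = 0.00755). LGR5 rose, NOTUM and DKK4, secreted inhibitors of Wnt signalling, fell (-2.39 and -1.78), and adjusted over the list alone 1 was higher and 4 lower. ICAM1, an adhesion molecule of the NF-kappaB and chemokine list, fell (-2.37, adjusted p = 0.00220; list adjusted p = 0.450; 3 lower adjusted over the list alone). Interferon response genes had a median of 0.02 against a test direction downwards (adjusted p = 0.835) and 0 members called by limma either way. Their array medians in the LIN28B primaries were 9.91, 9.53 and 7.70. The list passed upwards without LIN28B primary replicate 3, with a median of 0.45, 13 members higher and 2 lower (adjusted p = 1.97e-04). CD14 (-1.06) and CORO1A (-2.15) of the myeloid and lymphoid list fell (list adjusted p = 0.715), as did KRT5 (-2.00) and SFN (-0.57) of the skin keratinocyte list (0.715). TPM2, a tropomyosin, fell (-1.35) in the skeletal muscle list, whose median of -0.02 stood against a test direction upwards (adjusted p = 0.957). In the other cell type lists limma called 0 members over all genes. Their adjusted p was 0.976 for endothelium, 0.478 for lung epithelium, 0.113 for hepatocytes, 0.835 for adipocytes (median -0.02, mean 0.13) and 0.835 for erythroid cells (median 0.01, mean -0.01). The count was also 0 for enterocyte differentiation (adjusted p = 0.0817), enteroendocrine and Paneth cells (0.734; median -0.02, mean 0.06), epithelial junction and keratin (0.445) and mesenchymal transition (0.421). It was 0 again for endoplasmic reticulum stress (0.358), ribosome biogenesis (0.835), TGF-beta and BMP response (0.538) and p53 targets (0.715; median -0.07, mean 0.01). Adjusted over the list alone, 1 member was higher in the adipocyte list, 1 in TGF-beta and BMP response and 1 in epithelial junction and keratin, which also had 2 lower. The same adjustment gave 2 lower in the myeloid and lymphoid list, 2 in the skin keratinocyte list and 1 in the skeletal muscle list. MYC had 0.29 (adjusted p = 0.306) and DICER1, which cuts microRNA precursors, 0.40 (adjusted p = 0.491). The RNA-binding protein IGF2BP1 had 0.84 (adjusted p = 0.588), with 8.96, 8.60 and 6.25 in the LIN28B primaries, and 1.68 without the last of these (adjusted p = 0.00497).

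The second comparison, metastases against LIN28B primaries, asks how metastases differ from primary tumours of the same cells. FOS rose 5.35-fold (log2 fold change 2.42 ± 0.36 SE, n = 3 arrays per group, limma adjusted p = 0.0244), with EGR1 (2.06 ± 0.30, adjusted p = 0.0225) and FOSB (1.72, adjusted p = 0.0381), all transcription factors induced within minutes of a stimulus. DUSP1, a phosphatase that turns off MAP kinases, rose 4.88-fold (2.29 ± 0.26, adjusted p = 0.0116). FOS read 10.78, 11.04 and 11.91 in the metastases, 8.92, 9.44 and 8.12 in the LIN28B primaries and 9.25 to 9.44 in the vector primaries. EGR1 read 12.14, 12.76 and 12.68 in the metastases and 10.44, 9.94 and 11.04 in the LIN28B primaries, but 11.82, 11.41 and 12.10 in the vector primaries. Against the vector primaries the metastases' EGR1 did not pass (0.76, adjusted p = 0.158). The vector primaries read 7.36, 7.38 and 7.23 for FOSB and 9.06, 9.08 and 9.16 for DUSP1, and the metastases 8.21, 8.86 and 9.78 and 10.66, 10.68 and 11.37. Small noncoding RNAs made up the other 8 of the 12 largest rises. They included the spliceosomal RNAs RNU11 (1.99 ± 0.22, adjusted p = 0.0113) and RNU4-1 (1.47, adjusted p = 0.0193), the vault RNA VTRNA1-1 (2.33, adjusted p = 0.0380) and SNORA65, a guide for RNA modification (1.69, adjusted p = 0.0241). PDE8B, a phosphodiesterase, fell (-2.10, adjusted p = 0.0409), as did MUC13, a transmembrane mucin (-1.86 ± 0.30, adjusted p = 0.0272), and PLBD1 (-1.90). ZFAND1 (-1.72 ± 0.15, adjusted p = 0.00844), the kinase RPS6KA5 (-1.67) and HLTF, a chromatin remodeller (-1.58 ± 0.18, adjusted p = 0.0121), fell too. PROM1 had -1.04 (adjusted p = 0.153), LGR5 -0.47 (adjusted p = 0.637) and IGF2BP1 -1.66 (adjusted p = 0.179), which passed without LIN28B primary replicate 3 (adjusted p = 4.61e-04). In all, 458 genes changed, 71 upwards and 387 downwards, and 3940 had an unadjusted p under 0.05. The share of falls was 84.5%, and 69.7% of 452 genes after quantile normalization. Over 2-fold, 119 genes changed. With only the 6 arrays compared limma called 0 genes, so the calls rested on the spread shared with the vector primaries. Of the 24 largest rises and falls, 0 held whichever array was left out, and DUSP1 and ZFAND1 were lost only without metastasis replicate 3 (adjusted p = 0.0560 and 0.0549). The count was 3403 genes without LIN28B primary replicate 3, and 33 and 170 without LIN28B primary replicates 1 and 2. It was 140, 140 and 58 without vector primary replicates 1, 2 and 3, and 20, 113 and 0 without metastasis replicates 1, 2 and 3.

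Interferon response genes, the antiviral program, were lower in the metastases than in the LIN28B primaries (median -1.20, 29 members, camera adjusted p = 2.05e-07). This call and those of the 5 other lists that passed were lost with an estimated correlation (adjusted p = 0.724 for Wnt targets and 0.718 for the others), and fry called 0 lists. HERC6 was called over all genes (-1.23, adjusted p = 0.0272), and 7 members adjusted over the list alone. The array medians were 7.69, 7.72 and 7.86 in the metastases and 9.91, 9.53 and 7.70 in the LIN28B primaries, so that LIN28B primary replicate 3 lay at the level of the metastases. Without it, 23 members were lower and 1 higher (adjusted p = 1.80e-17). Proliferation was lower (median -0.34, 34 members, adjusted p = 1.58e-05). The mitotic kinases TTK (-1.03) and CDK1 (-1.15), TPX2 (-0.76) and the cyclin CCNB2 (-1.11) fell, and 12 members adjusted over the list alone. Oxidative phosphorylation was lower (median -0.38, 27 members, adjusted p = 4.24e-05). COX6C (-1.35), NDUFB5 (-1.02) and NDUFS1 (-0.54) fell, and 9 members adjusted over the list alone. These 3 lists held their call at the preset correlation whichever array was left out. Wnt targets were higher (median 0.70, 23 members, adjusted p = 0.0130), with 0 members called by limma over all genes or adjusted over the list alone. NKD1, a Wnt feedback inhibitor, had 1.73 (adjusted p = 0.0883). The array medians of Wnt targets were 9.08, 8.23 and 9.94 in the LIN28B primaries and 9.72 to 10.17 in the metastases. Without LIN28B primary replicate 3, 14 members were higher and 1 lower. p53 targets were lower (median -0.26, 23 members, adjusted p = 0.0161). CCNG1 fell by 0.79, and adjusted over the list alone 5 were lower and 2 higher. Hypoxia was lower (median -0.31, 29 members, adjusted p = 0.0191). KDM3A (-0.78), PDK1 (-0.86) and P4HA1 (-0.55) fell, and adjusted over the list alone 5 were lower and 1 higher. Wnt targets were lost without LIN28B primary replicate 2 (adjusted p = 0.0884) or metastasis replicate 2 (0.0818), and p53 targets without LIN28B primary replicate 1 (0.121). Hypoxia was lost without LIN28B primary replicate 1 (0.0529) or 2 (0.128) or metastasis replicate 2 (0.0962). Quantile normalization also ended the p53 (0.159) and hypoxia (0.324) calls, and without metastasis replicate 3 the number of lists was 10. Gained there were goblet cell downwards (0.0324) and erythroid (0.0413), hepatocyte (0.0413) and myeloid and lymphoid (0.0388) markers upwards. Goblet cell was also gained downwards without LIN28B primary replicate 1 (0.0425) or 3 (0.00238), and erythroid (0.0235) and myeloid and lymphoid (0.0213) markers upwards without LIN28B primary replicate 2. Endoplasmic reticulum stress was gained downwards without metastasis replicate 1 (0.0337). Leaving out the dimmer genes ended the hypoxia (0.256) and p53 (0.416) calls and gained TGF-beta and BMP response upwards (0.00659). The median of Wnt targets moved to 0.37 and 1.09 without LIN28B primary replicates 2 and 3, that of p53 targets to -0.15 without LIN28B primary replicate 1, and that of proliferation to -0.19 without metastasis replicate 3. The 23 other lists had adjusted p from 0.0608 to 0.988. In the epithelial junction and keratin list (median 0.01, mean -0.13, adjusted p = 0.321), the adhesion proteins DSC2 (-0.81), CDH17 (-0.96) and DSG2 (-0.75) and the junction protein MARVELD2 (-0.78) fell. Adjusted over the list alone 5 members were lower. S100A4, a calcium-binding protein of the mesenchymal transition list, rose (1.14, adjusted p = 0.0360; list adjusted p = 0.321; 1 adjusted over the list alone). IGF2BP3, an RNA-binding protein of the LIN28 and let-7 targets, fell (-1.08, adjusted p = 0.0272; list adjusted p = 0.341; 1 adjusted over the list alone).

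**Figure D3:**
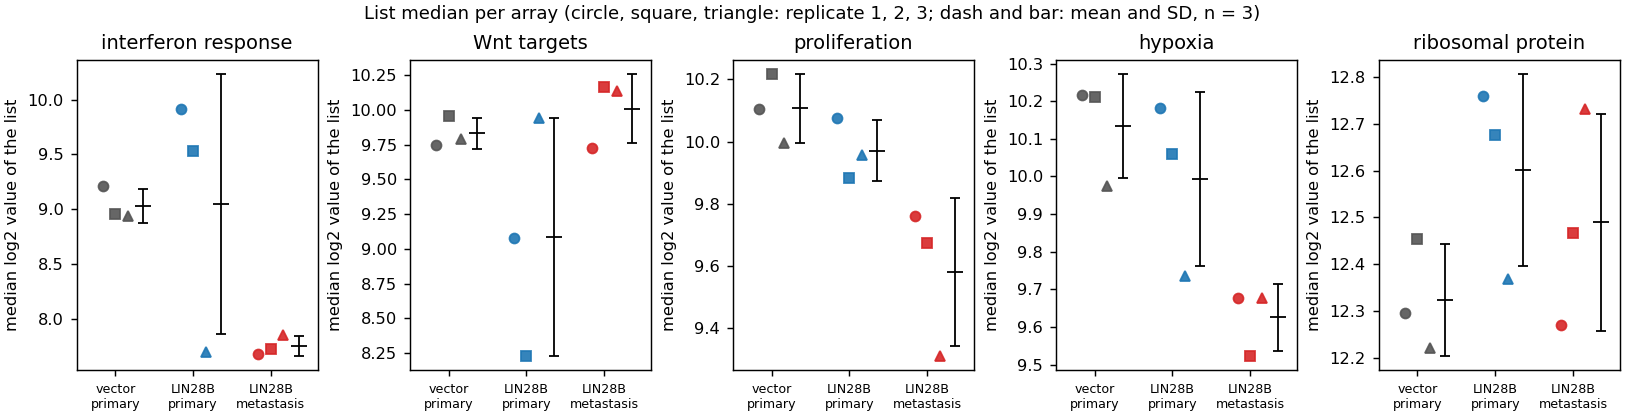
Median log2 intensity of 5 gene lists in each of the 9 arrays, by group; each point is 1 array. For the interferon response, LIN28B primary replicate 3 (7.70) and the metastases (7.69 to 7.86) lie below the other arrays (8.94 to 9.91), and for Wnt targets LIN28B primary replicates 1 and 2 (9.08 and 8.23) lie lowest.

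The comparison of metastases with vector primaries joins the difference of site with that of the transduced gene. SLC14A1, a urea transporter, rose (log2 fold change 3.82 ± 0.49 SE, n = 3 arrays per group, limma adjusted p = 0.00574). It read 6.61, 4.94 and 5.44 in the vector primaries, partly near background, so the size of the rise is uncertain. GASK1B (3.727, adjusted p = 0.0276) and ERVMER34-1 (2.965, adjusted p = 0.0264) had the next largest rises by limma. MTND2P28, a nuclear copy of a mitochondrial gene, rose 7.57-fold (2.92 ± 0.33, adjusted p = 0.00344). Whether its probes separate the copy from the mitochondrial gene was not known, so the rise may belong to either. CFTR (2.94, adjusted p = 0.0116), LGR5 (2.72, adjusted p = 0.0229) and PROM1 (1.84, adjusted p = 0.0211) were higher as well. MYC had 0.39 (adjusted p = 0.102) and passed after quantile normalization (0.54, adjusted p = 0.0241). SNORD116-24 (-5.47 ± 0.81, adjusted p = 0.00912) and SNORD116-1 (-4.67, adjusted p = 0.00165) fell. They read 5.14, 4.57 and 6.25, and 3.95, 4.14 and 4.57, in the metastases, mostly under the same lower quartile, so the size of these falls is uncertain. In all, 1382 genes changed, 325 upwards and 1057 downwards, and 4647 had an unadjusted p under 0.05. Of the genes called in LIN28B primaries against the same 3 vector arrays, 34 of 126 rises and 192 of 239 falls were called here in the same direction. Independent calls would share 2.23 and 13.8. The fold changes of both comparisons correlated across genes at 0.507, against 0.500 in 100 simulations of unchanged groups with shared controls. Their covariance was 0.0814 against 0.0244. The simulations shared 0 calls on average by limma. They held no changed genes, so this count was bound to be low and does not bear on the shared calls. The 3 control arrays are too few to be split, so the part of the overlap that comes from shared controls was not measured. SLC14A1, MTND2P28, SNORD116-24 and SNORD116-1 held whichever array was left out. CFTR was lost without vector primary replicate 3 (adjusted p = 0.0538) or metastasis replicate 3 (0.0503). LGR5 was lost without vector primary replicate 2 (0.0752) or 3 (0.0835) or metastasis replicate 2 (0.0725) or 3 (0.0837). PROM1 was lost without vector primary replicate 3 or metastasis replicate 1, 2 or 3 (adjusted p up to 0.0721). The count was 3208 without LIN28B primary replicate 3, and 246, 543 and 261 without vector primary replicates 1, 2 and 3. It was 488, 638 and 435 without metastasis replicates 1, 2 and 3, and 4030 with only the 6 arrays compared.

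Proliferation genes were lower in metastases than in vector primaries (median -0.52, camera adjusted p = 1.38e-09), with 8 members called over all genes and 17 adjusted over the list alone. This call and those of the 10 other lists that passed were lost with an estimated correlation (adjusted p = 0.543 for intestinal stem cell and 0.532 for the others). By fry 7 of the 11 passed, and interferon response (adjusted p = 0.0948), ribosomal protein (0.0948), intestinal stem cell (0.158) and fibroblast and smooth muscle (0.0670) did not. Interferon response was lower (median -1.23, adjusted p = 5.37e-07; 6 called, 13 adjusted over the list alone), as was hypoxia (median -0.44, adjusted p = 1.17e-06; 6 called, 16 lower and 1 higher adjusted over the list alone). Cholesterol synthesis was lower (median -0.51, adjusted p = 1.33e-04; 1 called, 7 adjusted over the list alone). Intestinal stem cell genes were higher (median 0.32, adjusted p = 0.00716). LGR5, PROM1, CD24 (1.52) and the adhesion molecule ALCAM (1.12) rose, and adjusted over the list alone 6 were higher and 1 lower. Ribosomal protein genes were higher (median 0.21, adjusted p = 0.00290; 1 called, 1 adjusted over the list alone). Hepatocyte markers were higher (median 0.17, adjusted p = 0.00541), with 1 member called, the fibrinogen chain FGA (2.05, from 5.06 to 5.23 in the vector primaries, near background), and 0 by limma adjusted over the list alone. Erythroid markers were higher (median 0.15, 7 members, adjusted p = 0.0423). HBB, a haemoglobin chain, rose (0.59), and 2 members passed adjusted over the list alone. The array medians of the hepatocyte and erythroid markers lay between 5.54 and 6.48. In this comparison genes with mean levels of 5.52 and 6.26 had median log2 fold changes of 0.112 and 0.086. Part of the shift of both lists therefore goes with level. Endoplasmic reticulum stress and amino acid response was lower (median -0.19, adjusted p = 0.0176). DNAJB9 (-1.37), a chaperone partner, and HERPUD1 (-0.88) fell, and 3 members adjusted over the list alone. Fibroblast and smooth muscle markers were lower (median -0.16, adjusted p = 0.0176), and the 1 called member, also adjusted over the list alone, was ACTA2, smooth muscle actin (-2.03). Epithelial junction and keratin genes were lower (median -0.23, camera adjusted p = 0.0256), with 4 called and 4 adjusted over the list alone. Genes with mean levels of 9.01, 9.68 and 11.02 had median log2 fold changes of -0.157, -0.186 and -0.195 here. The shifts of this list and of endoplasmic reticulum stress may therefore go with level. The enteroendocrine and Paneth cell and the NF-kappaB and chemokine lists passed by fry alone (adjusted p = 0.0353 each; camera 0.0582 and 0.463). Without vector primary replicate 2 the number of lists was 7. Lost there were endoplasmic reticulum stress (adjusted p = 0.0569) and the epithelial junction, erythroid and fibroblast lists (0.0542 each). Endoplasmic reticulum stress was also lost without metastasis replicate 3 (0.0628). Erythroid markers were also lost without vector primary replicate 1 (0.0602), LIN28B primary replicate 1 (0.0517) or 3 (0.0559) or metastasis replicate 1 (0.0789). Gained without LIN28B primary replicate 3 were p53 targets downwards (0.0255) and TGF-beta and BMP response upwards (0.0497). Enteroendocrine and Paneth cell genes were gained upwards without vector primary replicate 3 (0.0287) or metastasis replicate 3 (0.0487). Quantile normalization ended the calls of the hepatocyte (0.149), erythroid (0.416), epithelial junction (0.527) and endoplasmic reticulum stress (0.496) lists and gained TGF-beta and BMP response upwards (0.0170). Leaving out the dimmer genes ended the endoplasmic reticulum stress (0.297) and epithelial junction (0.420) calls and left too few fibroblast, erythroid and hepatocyte markers to test. Gained upwards there were TGF-beta and BMP response (0.00616), Wnt targets (0.0212) and LIN28 and let-7 targets (0.0260). The ribosomal protein median was 0.12 without vector primary replicate 3 and 0.13 without metastasis replicate 3.

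The last comparison set the mean of both LIN28B groups against the vector primaries. A call here can come from 1 of these groups; 34 rises and 192 falls were called in each group by itself. CFTR (log2 fold change 3.10 ± 0.40 SE, n = 3 arrays per group, limma adjusted p = 0.00632), LGR5 (2.95 ± 0.47, adjusted p = 0.0148) and SLC14A1 (2.94 ± 0.42, adjusted p = 0.0103, from a level partly near background) rose most. PROM1 (2.36 ± 0.31, adjusted p = 0.00650) and MTND2P28 (5.65-fold, adjusted p = 0.00362) followed, where the probes of MTND2P28 may also read the mitochondrial gene. The 5 largest falls were SNORD116 copies, led by SNORD116-24 (-5.12 ± 0.70, adjusted p = 0.00782), with SNORD116-1 at -4.47 ± 0.39 (adjusted p = 8.94e-04), where the size is again uncertain. MYC had 0.34 (adjusted p = 0.124) and passed after quantile normalization (0.43, adjusted p = 0.0376). SLC2A3 read 8.21 to 9.13 in all 6 LIN28B arrays and 11.85 to 12.31 in the vector primaries. In all, 880 genes changed, 188 upwards and 692 downwards, and 3787 had an unadjusted p under 0.05. CFTR, MTND2P28, PROM1 and SNORD116-1 held whichever array was left out. LGR5 was lost without vector primary replicate 2 (adjusted p = 0.0663) or 3 (0.0833), and SLC14A1 (0.0667) and SNORD116-24 (0.0552) without vector primary replicate 3. The count was 2736 without LIN28B primary replicate 3, and 196, 215 and 146 without vector primary replicates 1, 2 and 3. It was 397, 414 and 408 without metastasis replicates 1, 2 and 3.

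Proliferation was lower in the mean of both LIN28B groups than in the vector primaries (median -0.37, camera adjusted p = 2.24e-07), with 2 members called and 12 adjusted over the list alone. This call and those of the 8 other lists that passed were lost with an estimated correlation (adjusted p = 0.570 to 0.649). By fry only hypoxia of the 9 passed (adjusted p = 0.0427), beside NF-kappaB and chemokine (0.0427), which camera did not call (0.423). Hypoxia (median -0.35, adjusted p = 1.60e-05; 5 called, 13 lower and 1 higher adjusted over the list alone) and cholesterol synthesis (median -0.42, adjusted p = 1.34e-04; 2 called, 9 adjusted over the list alone) were lower as well. Interferon response was lower (median -0.59, adjusted p = 7.58e-04; 1 called, 0 by limma adjusted over the list alone). Its array medians in LIN28B primary replicates 1 and 2, 9.91 and 9.53, lay above the 8.94 to 9.21 of the vector primaries, and without LIN28B primary replicate 3 the list's median was -0.33, with 9 members lower. Ribosomal protein genes were higher (median 0.25, adjusted p = 1.08e-05; 1 called, 6 adjusted over the list alone). Hepatocyte markers were higher (median 0.17, camera adjusted p = 0.00953) with 0 members called by limma either way. Genes with mean levels of 5.52 and 6.26 had median log2 fold changes of 0.069 and 0.059 here, so part of this shift goes with level. Intestinal stem cell genes were higher (median 0.18, adjusted p = 0.0119; 4 called, and 5 higher and 1 lower adjusted over the list alone), with a median of 0.12 without vector primary replicate 2 and 0.07 without LIN28B primary replicate 3. Fibroblast markers (median -0.14, or -0.08 without vector primary replicate 1, adjusted p = 0.00289; 2 called, 4 adjusted over the list alone) and endoplasmic reticulum stress (median -0.15, adjusted p = 0.0466; 2 called, 2 adjusted over the list alone) were lower. Without LIN28B primary replicate 3, intestinal stem cell (adjusted p = 0.120), fibroblast (0.0528) and endoplasmic reticulum stress (0.0930) lists were lost. Gained there were enterocyte differentiation (0.0309) and oxidative phosphorylation (0.0445) upwards, and without vector primary replicate 3 epithelial junction and keratin downwards (0.0127). Endoplasmic reticulum stress was also lost without vector primary replicate 2 (0.173) or metastasis replicate 2 (0.0633) or 3 (0.142). Genes with mean levels of 9.01 and 9.68 had median log2 fold changes of -0.11 and -0.144. The endoplasmic reticulum stress median of -0.15 may therefore go with level. Quantile normalization ended the hepatocyte (0.109) and endoplasmic reticulum stress (0.488) calls, and centring the arrays on their medians the latter (0.0526). Gained upwards after quantile normalization were LIN28 and let-7 targets (0.0162) and oxidative phosphorylation (0.0264). Leaving out the dimmer genes ended the endoplasmic reticulum stress call (0.358), gained LIN28 and let-7 targets upwards (0.00857) and left too few hepatocyte and fibroblast markers to test. With the replicate number as a block, epithelial junction and keratin was gained downwards (0.0487).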

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

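All tests of explanations in this part were chosen only after the result was seen. LIN28B primary replicate 3 resembled the metastases more than its own group. Its mean correlation across genes was 0.978 with the metastases, 0.968 with the vector primaries and 0.947 with the other LIN28B primaries. It thus lay closer to both other groups than to its own, and these correlations do not settle which LIN28B primaries stand apart. A swap of labels with a metastasis would also leave a primary tumour under a metastasis label. Of the metastasis arrays, 0 lay closer to LIN28B primary replicates 1 and 2 than to their own group. This argues against a swap only if those replicates are typical primaries. The difference between its mean correlations with the metastases and with the other LIN28B primaries was 0.0301 as deposited and 0.03 after quantile normalization. A correlation hardly responds to the shift or scale of an array's values, so this test says little on differing value distributions. Against a metastasis under a primary label stands its position between the other primaries of both kinds (0) and the metastases (1). Its median was 0.663 over 1425 genes chosen without it (quartiles 0.228 and 1.02), against 0.842 to 0.915 for each metastasis when held out. The quartiles overlap and this is 1 array, so a metastasis unlike the other 3 stays open. A difference between tumours of the same cells, which the design cannot test, stays open too. The small-RNA median of LIN28B primary replicate 3 was 7.81, against 8.58 to 9.01 in the metastases. That difference may come from the recovery of small RNA, so it does not tell which tissue the array measured.

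SNORD116 copies were lower in the LIN28B groups: 13 of 20 measured copies were called in the mean of both LIN28B groups against vector primaries, where the median log2 fold change of the 20 was -1.37, and 11 in LIN28B primaries against vector primaries. Lower recovery of small nucleolar RNA would lower the others too, but the 135 others had a median of 0.257 (quartiles 0.04 and 0.57), with 0 called lower by limma and 14 higher. Whether the copies are separate signals or 1 signal read by near-identical probes cannot be told apart. The median pairwise correlation of their deviations from the group means was 0.446. Separate copies that vary together would also correlate, so this value does not decide. Of the neighbours in the region UBE3A fell in the metastases, against vector primaries (-0.72, adjusted p = 0.0196) and against LIN28B primaries (-0.77, adjusted p = 0.0326). It had 0.04 in LIN28B against vector primaries, where limma called 0 neighbours. MAGEL2, NDN, PWAR6, ATP10A and the SNORD115 copies were called in 0 comparisons by limma. In the vector primaries the SNORD115 copies read at most 4.46, PWAR6 3.53 to 3.54, NDN 5.46 to 5.47, ATP10A 5.57 to 5.68 and MAGEL2 5.78 to 6.01. These values lie near or under the arrays' lower quartile of 5.39 to 5.61, so a fall could hardly show. SNRPN, SNURF and IPW were not among the measured genes. The fall of the SNORD116 copies may come from LIN28B or from the selection of transduced cells, which the design confounds, and whether it reaches beyond them stays open.

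Small RNAs were higher in the metastases than in the LIN28B primaries. Of 154 small nucleolar and spliceosomal RNAs, SNORD115 and SNORD116 left aside, 132 had a positive change, 20 were called higher and 0 lower by limma, and the median was 0.429, where 10000 random lists of matched level had a median of 0.019 and the class lay at their percentile 100. The narrower value distribution of the metastasis arrays is argued against by the same median after quantile normalization, 0.468. A higher recovery of small RNA in the metastasis samples is consistent with the shift of the whole class and may be its source. A difference between metastasis and primary tumours in these RNAs stays open too, since no label tells how the samples of each group were handled.

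Transcript clusters with several gene names or none lay outside the gene comparisons, and some gave signals above the vector primaries. Between LIN28B and vector primaries 23 of 9538 such clusters were higher and 30 lower. Between metastases and vector primaries 471 were higher and 111 lower, with a median log2 fold change of 0.16 over all of them. These clusters are dim, and dim genes with 1 name shifted upwards as well, by a median of 0.11 in the tenth with a mean level of 5.52, so part of the shift goes with level.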

How the results depend on the processing

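Among the tests in this part, quantile normalization together with leaving out LIN28B primary replicate 3 was chosen only after the data were seen. Under the alternatives 0 named genes, and 0 lists already past the threshold, passed in the opposite direction, but the interferon response, not past it between LIN28B and vector primaries (test downwards), passed upwards without LIN28B primary replicate 3 (adjusted p = 1.97e-04). Of 1512 results for named genes under the alternatives, 1165 kept their side of the threshold, 325 lost and 22 gained the call, and of 589 for lists already past it 457 kept it and 132 lost it. In the order LIN28B primaries against vector, metastases against LIN28B primaries, metastases against vector and both LIN28B groups against vector, the counts of changed genes were 2316, 2959, 4324 and 3305 with arrayWeights, 144, 60, 778 and 446 with the replicate number as a block, and 2954, 3905, 3096 and 2555 with the added pair of choices. A fit of only the groups compared gave 36, 0 and 4030 for the first 3 (limma, where all 9 arrays gave 458 for the second and 3940 at an unadjusted p under 0.05); it left out the arrays of a group with another spread, and the cause of the other shifts was not tested. The replicate numbers gave no clear sign of a pairing. In 1 of 9 pairs of arrays with the same number in 2 groups, that number correlated best. With 3 arrays per group and LIN28B primary replicate 3 apart from its group, this cannot show that the samples are unpaired. Leaving out each array in turn gave 70 to 2706, 0 to 3403, 246 to 3208 and 146 to 2736 genes and 3 to 11, 4 to 10, 7 to 12 and 8 to 10 lists. Lists past the threshold by an estimated correlation were 0, 0, 0 and 0; by fry, which asks another question, 0 in the first, 0 in the second and 2 in the last; and without the dimmer genes 4 in the first, where fewer genes were tested. Dropping the dimmer genes moved the median of all fold changes by -0.15 (metastases against vector) and -0.11 (both LIN28B groups); dim genes lie near background, which limits what LIN28B's own probes can show. The pseudocount alternatives did not apply to log2 values.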

Other observations

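The tests of neighbouring genes in this part, and the genes named in its first paragraph, were chosen only after the results were seen; the splits of the samples were planned. Between LIN28B primaries and metastases, JUNB (log2 fold change 1.36 ± 0.20 SE, limma adjusted p = 0.0245), ZFP36, which destabilises messenger RNAs (1.41 ± 0.24, adjusted p = 0.0306), IER3 (0.90 ± 0.14, adjusted p = 0.0269) and JUN (adjusted p = 0.0427) were higher in the metastases. IER2 (1.15, adjusted p = 0.0699) and ATF3 (0.47, adjusted p = 0.374) did not pass. JUNB had -0.93 between LIN28B and vector primaries (adjusted p = 0.0577).

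Genes called lower in the mean of both LIN28B groups than in the vector primaries lay next to one another more often than shuffled labels gave. Along GRCh38.p14, the 692 genes made 53 neighbouring pairs, against a mean of 26.1 and a highest of 50 in 10000 shuffles (permutation p = 1e-04, one-sided, the smallest they can give). Without small RNAs and without pairs sharing the first letters of their names, 679 genes made 38 pairs, against a mean of 22.9 and a highest of 41 (permutation p = 0.0022, one-sided). The longest run outside SNORD116 held 4 zinc finger genes, ZNF738 (-2.52), ZNF493 (-1.31), ZNF429 (-1.93) and ZNF100 (-1.57). Its pairs are not among the 38, since these genes share the start of their names. Another run held TPM2 (-1.54), TLN1 (-0.63) and CREB3 (-0.91). The shuffles were not matched for level, and bright genes shifted downwards in this comparison. Genes with a mean level of 11.02 had a median log2 fold change of -0.153, and those at 4.5 had 0.067. The excess of pairs may therefore come from where bright genes lie, which the shuffles cannot tell from an effect on whole stretches. Genes called higher were not tested in this way. A hypothesis left open is that stretches of chromosome were lost or silenced in the cells that founded the LIN28B tumours. This may underlie part of the falls, but no copy number or methylation was measured here.

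Other splits of the samples were counted for each comparison. For LIN28B against vector primaries, the real split was the 1 of 10 with as many genes (365; highest other 3). For metastases against LIN28B primaries it was likewise 1 of 10 (458; highest other 0), and for metastases against vector primaries 1 of 10 (1382; highest other 0). In these 3 comparisons 10 splits are too few for a share under 0.05. For both LIN28B groups against vector primaries 2 of 100 splits drawn, the real one included, gave as many (880, highest other 1251). This share is under 0.05, but it concerns only how these 9 arrays were split. The samples may not be separate animals or transductions, so a chance difference between the tumours is not excluded. The split with 1251 genes set the metastases apart from both groups of primaries, which is a structure of the samples.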
